A study of Mus musculus with 5 samples.

How the data were processed

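Poly(A) RNA from whole mouse mammary glands was sequenced in 5 libraries, 2 from wild-type animals and 3 from animals described as Nfib-null. Per the labels' protocols, glands of outbred mice were taken on the day of birth, less than 12 hours after delivery, with the lymph nodes removed. RNA was extracted with TRIzol and cleaned on a column, and libraries were made with the TruSeq RNA kit and sequenced on an Illumina HiSeq instrument. CASAVA, TopHat and the mouse build mm9 are named per the submitters' processing notes, without versions. The counting tool, the gene annotation and the reads used as the denominator are not given in the sources used here. No label states whether strand was used in counting, so reads of overlapping genes on opposite strands cannot be separated here.

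The values analysed were deposited by the authors as RPKM (reads per kilobase of gene, scaled to the number of mapped reads), per the file headers, for 22609 genes in 2 columns. Each column holds a value per gene for a whole group, so no value of a single library entered the analysis. The name of one column is the one shared by the titles of the wild-type libraries. The name of the other, NfibFF-WC, is not spelled out in the labels, which do not say either whether the gene was deleted in all cells or in some, and that column was assigned to the Nfib-null group by elimination, since the series has 2 groups. It is called the Nfib-null column here. In that column 84.4% of the 12205 values written with 10 decimals ended in repeating 3s or 6s, which a mean of 3 values gives. In the wild-type column 67 values had 10 decimals and 0% of them ended so.

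Exact ties were counted among genes at 100 RPKM or more. In the wild-type column 8 of 489 such genes shared their value with another gene, against a mean of 0.04 in 100 random draws, and in the Nfib-null column 0 of 544 did, against 0.08. Wap and Glycam1 held the same value, as did Lalba and Spp1, Rpl4 and Rpl19, and P4hb and Rps14. Such ties can arise from a rank-based normalization of the libraries within a group. No label states one. Such a normalization would change untied values as well, so wild-type values in general, and those of the tied genes above all, are approximate.

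Depth was estimated from the low values, which were taken to lie at whole multiples of the value of 1 read in a gene of known length. Lengths were taken from genes with a single transcript in the GENCODE annotation of GRCm38, for 344 genes in the wild-type column and 434 in the other. As many steps were taken in each column as its group has libraries, so their number was set and not found. The steps corresponded to about 17800000 and 14800000 reads for the wild-type libraries and 34100000 and 27000000 for 2 Nfib-null libraries. A weaker step corresponded to about 20700000 for the remaining Nfib-null library. At 1 RPKM a gene of 1 kb would thus hold about 32.6 reads over the wild-type group and 81.8 over the Nfib-null group. These depths are approximate. A rank-based normalization, from which the ties in the wild-type column could come, would not keep low values at such multiples. The wild-type depths therefore hold only if low values were not changed in that way. No coordinates are given, because the submitters' build differs from the genome used for the lengths.

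The analysis planned before the data were examined was limma on log2 values with camera and fry for gene lists, an exact permutation test for the milk protein share, a replicate block and the omission of each library in turn. All of these need values per library, and none could be run on group means. No p-value, standard deviation or standard error is therefore given, and a difference between the columns has no replicate check. A difference is described by its size alone, and a gene is called higher or lower from at least 2-fold, a limit taken after the columns had been seen.

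Genes with a mean of at least 1 RPKM over the 5 libraries were kept, with the group means weighted by 3 and 2 libraries. This left 12511 genes and removed 10098. Each column was divided by its median-ratio factor, 1.153 for the Nfib-null column and 0.867 for the wild type, which sets the median log2 ratio of 0.41 between the columns to 0. Fold changes are differences of log2(scaled RPKM + 1), Nfib-null minus wild type, a scale that understates the change of genes with low values. RPKM values in the text are as deposited, before that scaling. Quantile normalization, equal sums without the 20 genes of highest mean, the values as deposited, pseudocounts of 0.1 and 5, no filter, and a minimum mean of 5 RPKM were fixed as alternatives before the data were examined. Fold limits of 1.5 and 4 and scaling to the luminal epithelial list were added afterwards.

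A total of 27 gene lists with 543 entries were fixed before the data were examined, and 11 genes stand in more than 1 list. For each list the members at least 2-fold higher or lower were counted. The median of its members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression to match its members. A median below the 0.5 or above the 99.5 percentile is reported as outside the central 99% of random lists. This percentile describes these libraries and is not a p-value, and it took the place of the planned list tests after the columns had been seen. Lists on the circadian clock and on fatty acid oxidation were written after the values had been seen and appear only among the additional observations.

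Named genes were chosen by a rule fixed beforehand: the 4 NFI genes, the 10 largest differences in each direction without unnamed predicted genes and immunoglobulin or T cell receptor segments, up to 4 members of each list, and the 5 genes of highest mean. The adjusted p of 0.05 in that rule was replaced by the 2-fold limit, and its condition on single libraries was dropped. For a list with no member beyond the limit, the 2 members of largest absolute fold are given as values. Genes named outside the rule are marked as such, and 3 genes that the rule names are not reported here.

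The procedure was tested on 2 simulated columns made from the wild-type column with log-normal noise (SD 0.15 on the natural log scale), a set of 200 genes changed 4- or 8-fold in either direction and the 10 most abundant genes lowered 4-fold. On 12365 simulated genes it returned a scale factor of 1.5 where 1.5 was put in. It placed 97.5% of genes at a 4-fold decrease in the right direction, and 100% of those at an 8-fold decrease or at a 4-fold or 8-fold increase. It called 13 of 12164 unchanged genes, and 1.3% of random lists fell outside the central 99%. The noise was set and not measured from animals. Nearly all simulated genes were unchanged, and the 200 changed genes went in both directions, so the scale factor could hardly be missed. The simulation therefore does not test the scaling for columns in which many genes differ.

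A total of 4088 genes are listed at 0 in both columns. They include Hmgcs1, a gene of cholesterol synthesis used by most cells, and the globin genes Hba-a1, Hba-a2 and Hbb-b2, while the globin entry Beta-s stood at 476 and 209 RPKM. A listed 0 is therefore not read as absence. Genes with near-identical copies, such as Saa1 and Saa2, Lyz1 and Lyz2, Rpl30 and the globins, and Mir680-2, which can share reads with other transcripts, are uncertain. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.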

Results

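Gene expression was measured by RNA sequencing in mammary glands of mice on the day they gave birth, in 2 wild-type and 3 Nfib-null libraries. Nfib encodes nuclear factor I/B, a DNA-binding transcription factor of the NFI family. The series asks how much of the expression that pregnancy induces in the gland depends on NFIB together with STAT5, the transcription factor that carries the prolactin signal into the nucleus. The tissue was whole gland without lymph nodes, so that milk-producing epithelium, fat, connective tissue, vessels and immune cells all contributed RNA. The values were the authors' group means in RPKM, with a single value per gene for each group, and the comparison therefore had no replicate check and no test. About 17800000 and 14800000 reads lay behind the wild-type mean and about 34100000, 27000000 and, less clearly, 20700000 behind the Nfib-null mean, as estimated from the smallest steps between values. A gene of 1 kb at 1 RPKM thus rests on about 32.6 reads in the wild type and 81.8 in the Nfib-null group. The number of steps was set to the number of libraries in each group. The wild-type depths hold only if low values were not changed by a rank-based normalization, which exact ties in that column leave possible.

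The targeted gene was examined first. Nfib stood at 55.3 RPKM in the Nfib-null column and at 33.7 RPKM in the wild-type column, a log2 difference of 0.30 after scaling, so it was not lower in the column assigned to the Nfib-null glands. Scaled to luminal epithelial genes, a choice made after the values had been seen, the difference was −0.32. A whole-gene RPKM can include reads from exons outside the deleted part and from cells that keep the gene, so it does not check the assignment of the columns. The labels do not say whether the gene was deleted in every cell of the gland or in some of them, and Nfib-null stands here for the submitters' term. All directions below are between the Nfib-null column, assigned by elimination, and the wild-type column, assigned from its name. The other family members were Nfic (37.1 against 21.9 RPKM, log2 0.34), Nfia (13.5 against 6.83, 0.52) and Nfix (43.2 against 19.5, 0.71). None of the 4 NFI genes differed by 2-fold, although Nfix did with values as deposited (1.11), and their median of 0.43 (percentile 93.0 of random lists) was −0.16 with scaling to luminal genes.

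The Nfib-null column held far less milk protein mRNA and more mRNA of fat, matrix and macrophage genes than the wild-type column. The 22 milk protein genes made up 66.4% of the summed RPKM in the wild type and 30.9% in the Nfib-null column. The 7 genes for the caseins, whey acidic protein (Wap) and alpha-lactalbumin (Lalba) alone made up 50.9% and 24.8%. Among 12511 genes at a mean of 1 RPKM or more, 869 were at least 2-fold higher in the Nfib-null column, 747 were at least 2-fold lower, and 10895 (87.1%) lay within 2-fold. Differences of at least 4-fold were split the other way, with 91 genes higher and 154 lower.

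The split between higher and lower genes depended on the scaling. After median-ratio scaling 53.8% of the genes beyond 2-fold were higher, after quantile normalization 53.9%, and after scaling to equal sums without the 20 most abundant genes 68.2% (1173 higher, 548 lower), with the median of all genes shifted by 0.15. With values as deposited 1800 genes were higher and 369 lower (83.0% higher), with a shift of 0.35. With scaling to luminal epithelial genes 264 were higher and 2591 lower, with a shift of −0.54. Quantile normalization, which is not a uniform shift, shared 747 of the 869 higher and 639 of the 747 lower genes with median-ratio scaling.

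**Figure D1:**
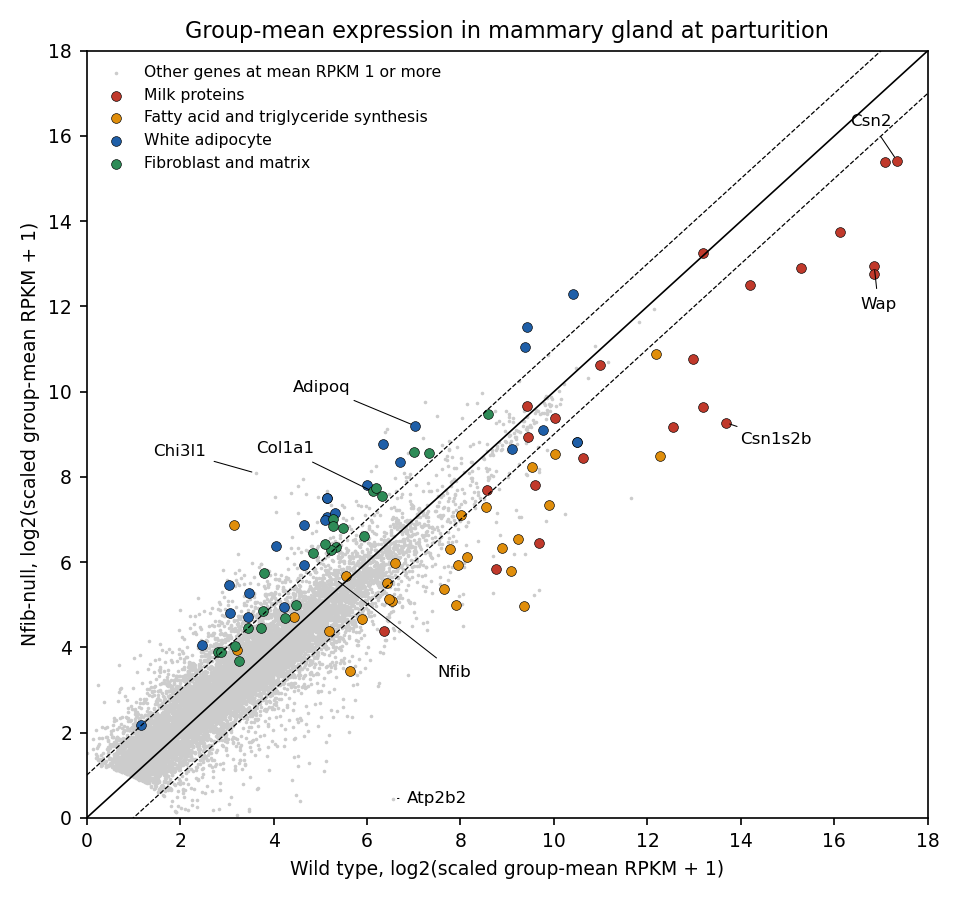
Each point is a gene, placed by log2(scaled group-mean RPKM + 1) in the wild-type column (x axis) and in the Nfib-null column (y axis), with milk protein, fatty acid and triglyceride synthesis, white adipocyte and fibroblast genes in colour. The solid line marks equal values and the dashed lines 2-fold differences: 16 of 22 milk protein genes lie below the lower dashed line and 20 of 24 adipocyte genes above the upper one, while Nfib lies between the dashed lines.

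Among named genes that were lower, the largest difference with the pseudocount of 1 was in Atp2b2, the plasma membrane calcium pump that moves calcium into milk. It stood at 0.426 RPKM in the Nfib-null column and 81.1 RPKM in the wild type (log2 −6.11). Next came the casein gene Csn1s2b (log2 −4.40), Olah, the thioesterase that releases medium-chain fatty acids (−4.38), the phosphate transporter Slc34a2 (−4.35), and Cidea, a lipid droplet protein needed for milk fat secretion (−4.33). Gsdmc, a gasdermin, stood at 0.374 against 19.7 RPKM (−4.16). Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 207 against 2776 RPKM (−4.15). Its wild-type value lay above that of the ribosomal protein gene Rplp1 (1024 RPKM). Reads from other transcripts cannot be excluded, so the difference of Lars2 is uncertain. Glycam1, a mucin-like milk protein, stood at 8021 against 102755 RPKM (−4.09), the membrane protein gene Steap1 at 1.33 against 28.6 RPKM (−3.98), and the microRNA host entry Mir680-2 at 0.529 against 18.4 RPKM (−3.93). The order depended on the pseudocount, because several of these genes had low values. With a pseudocount of 5, Csn1s2b (−4.40) stood ahead of Atp2b2 (−4.20). With 0.1, Gsdmc (−5.75), Mir680-2 (−5.25) and Steap1 (−4.72) stood ahead of Csn1s2b (−4.41).

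At the other end was Chi3l1, a secreted chitinase-like protein, at 313 RPKM in the Nfib-null column and 9.80 RPKM in the wild type (log2 4.47). Pdk4, the kinase that shuts off pyruvate oxidation, stood at 134 against 6.87 RPKM (3.72), Fcgbp, a mucus-associated protein, at 212 against 13.2 (3.51), and Angptl4, a secreted inhibitor of lipoprotein lipase, at 284 against 20.5 (3.33). The metallothionein Mt2 (3.28), the cytochrome P450 Cyp2e1 (3.26), the proton pump subunit Atp6v1b1 (3.13), the secreted carbonic anhydrase Car6 (2.96), Pck1, the cytosolic enzyme of gluconeogenesis and glyceroneogenesis (2.90), and the receptor tyrosine kinase Kit (2.89) completed the 10 named genes of largest difference in this direction.

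The 5 genes of highest mean were all milk protein genes, and all 5 were lower in the Nfib-null column. Csn2, beta-casein, stood at 50689 against 143846 RPKM (log2 −1.92), Csn1s2a at 49694 against 120513 (−1.69), Wap at 9085 against 102755 (−3.91) and Csn1s1 at 15930 against 61562 (−2.36). With quantile normalization, which gives the top ranks of both columns the same values, Glycam1 stayed lower (−1.70), Wap came within 2-fold (−0.65), Csn2 and Csn1s2a did not differ (0) and Csn1s1 turned to the opposite sign within 2-fold (0.77). Of the 22 milk protein genes, 16 were at least 2-fold lower and 0 higher, and their median of −2.07 lay below every one of 10000 random lists (percentile 0). Lalba, the subunit that turns galactosyltransferase into lactose synthase, stood at 914 against 8156 RPKM (−3.57). The 6 members within 2-fold, named after their values had been seen, were Ltf, Mfge8, Muc1, Muc15, Spp1 and Plin2. Quantile normalization left 10 members lower and 1, Spp1, higher (2.40), with a median of −0.59.

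Genes that supply milk fat, sugar and ions were lower with the milk proteins. In the fatty acid and triglyceride list 20 of 29 genes were lower and 2 higher (median −1.43, percentile 0). Olah stood at 35.3 against 572 RPKM, Fabp3, a fatty acid carrier, at 414 against 4261 RPKM (−3.77), and the desaturase Fads2 at 62.9 against 469 RPKM (−3.29). The 2 higher members were Pdk4 and Dgat2 (209 against 29.9 RPKM, 2.36), the latter also in the adipocyte list. In the cholesterol synthesis list 16 of 20 genes were lower and 0 higher (median −1.66, percentile 0). Insig1, a sterol-regulated brake on the pathway, stood at 41.4 against 216 RPKM (−2.76), and the pathway enzymes Fdps, Lss and Cyp51 differed by −2.54, −2.27 and −2.24.

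In the glucose and lactose list 8 of 15 genes were lower and 1 higher (median −1.16, percentile 0), and 5 were lower with values as deposited. Besides Lalba these included B4galt1, the catalytic part of lactose synthase (154 against 547 RPKM, −2.23), and the glucose transporter Slc2a1 (23.5 against 82.5, −2.17). The higher member, named after its value had been seen, was Slc2a4, the insulin-responsive glucose transporter, also in the adipocyte list (1.26). In the list of ion and amino acid transporters 11 of 18 were lower and 2 higher (median −1.32, percentile 0). Atp2b2, Slc34a2 and the zinc transporter Slc30a2 (1.52 against 19.0 RPKM, −3.31) were lower, and Atp6v1b1 was higher at 166 against 13.5 RPKM. The other higher member, named after its value had been seen, was the glutamine transporter Slc1a5 (2.12).

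In the list of the endoplasmic reticulum and secretory pathway 20 of 32 genes were lower and 0 higher (median −1.17, percentile 0). The chaperone-associated genes Sdf2l1 and Creld2 differed by −2.31 and −1.97, Ssr4, a translocon subunit, by −1.81, and the COPII coat gene Sec23b by −1.76. With values as deposited 9 of the 32 were lower, and the median was −0.77.

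The prolactin and STAT5 list did not move in a single direction. Of 18 genes, 6 were lower and 3 higher in the Nfib-null column, and the median of 0.03 (percentile 74.2) lay inside the range of random lists and turned to −0.0004 with quantile normalization and −0.56 with scaling to luminal genes. With values as deposited 3 were lower and 4 higher, with a pseudocount of 5 there were 5 lower and 1 higher, and with scaling to luminal genes 7 lower and 0 higher. Cidea, Id2 (56.9 against 163 RPKM, −1.91), an inhibitor of differentiation needed for alveoli, and Elf5, the ETS factor of alveolar cells (321 against 711 RPKM, −1.56), were lower. Bcl2l1, a survival gene, was higher at 29.5 against 7.77 RPKM (1.42), as were Socs3 (1.33) and Igf1 (1.06), named after their values had been seen. Values of genes of the pathway itself, named after they had been seen, were 55.7 against 63.7 RPKM for Stat5a, 26.6 against 22.1 for Stat5b, and 15.5 against 9.58 for Jak2. The prolactin receptor gene Prlr stood at 9.13 against 18.0 RPKM (−1.29), and Cish, a feedback inhibitor and STAT5 target, at 21.3 against 38.7 (−1.23), both within 2-fold with values as deposited (−0.91 and −0.83).

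Markers of luminal epithelium, the layer that makes milk, were not lower with the milk genes. Of 18 luminal genes 5 were higher and 2 lower (median 0.62, percentile 99.99), and with values as deposited 10 were higher and 1 lower. Kit (63.9 against 5.72 RPKM, 2.89), Aldh1a3 (39.8 against 3.63, 2.78), both markers of luminal progenitor cells, and the tight junction genes Cldn4 (2.16) and Cldn3 (1.74) were the largest. The keratin genes Krt8 and Krt18, named after their values had been seen, stood at 337 against 167 RPKM and 467 against 187 RPKM, within 2-fold after scaling. The remaining higher member was Krt7 (1.63), and the 2 lower members were Elf5 and Cldn8 (−1.40), with Krt7 and Cldn8 named in the same way.

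In the hormone-sensing luminal list 4 of 10 genes were higher and 1 lower (median 0.77, percentile 99.8). The higher ones included Cd14 (639 against 74.2 RPKM, 2.68), a receptor for bacterial lipopolysaccharide that also stands in the macrophage and involution lists, Calca (1.47), the pioneer factor Foxa1 (1.14) and, named after its value had been seen, Cited1 (1.12). The lower one was Prlr. Cd14, the largest of the higher ones, does not mark hormone-sensing cells alone. Esr1, named after its value had been seen, stood at 6.25 against 5.80 RPKM (−0.26), and Pgr and Areg lay below the minimum. Calca (3.16 against 0.305 RPKM) and Foxa1 (3.79 against 0.816 RPKM) had low values. With a pseudocount of 5 there were 1 higher and 0 lower, and with scaling to luminal genes 2 higher and 1 lower. Of 16 basal and myoepithelial genes 2 were higher, Sparcl1 (1.68) and Tspan8 (1.27), and 0 lower. Their median of 0.25 (percentile 97.8) lay inside the range of random lists and was −0.32 with scaling to luminal genes.

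Fat cell genes were higher in the Nfib-null column. Of 24 white adipocyte genes 20 were higher and 1, Thrsp, which the fatty acid list also holds, was lower (log2 −1.67), and the median of 1.81 lay above every random list (percentile 100). The lipid droplet gene Cidec stood at 503 against 69.3 RPKM (2.43), the retinol carrier Rbp4 at 50.1 against 6.34 (2.42), and leptin (Lep) at 94.7 against 13.5 (2.32). Adipoq, the gene of the hormone adiponectin, named after its value had been seen, stood at 677 against 112 RPKM. The brown adipocyte list had only 4 of 10 genes above the minimum. Cidea and Otop1 (−2.56) were lower and Cox8b (1.30) higher, and the median of −1.43 (percentile 0.12) turned to 0.04 without the filter on low values. The milk lipid gene Cidea thus stood apart from the fat cell genes of the adipocyte list.

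Connective tissue and macrophage genes were also higher. Of 24 fibroblast and matrix genes 16 were higher and 0 lower (median 1.07, percentile 100), among them fibronectin (Fn1, 60.7 against 11.1 RPKM, 1.96), Dpt (1.74), Serpinf1 (1.60) and decorin (Dcn, 438 against 110 RPKM, 1.58). With scaling to luminal genes 2 of the 24 were higher (median 0.50), and with a pseudocount of 5 there were 11 (median 0.96). Of 17 macrophage genes 11 were higher and 0 lower (median 1.11, percentile 100), with Cd68 at 49.1 against 11.2 RPKM (1.65), the complement gene C1qc at 95.3 against 26.1 (1.43) and the scavenger receptor Cd163 at 13.2 against 3.36 (1.35). With scaling to luminal genes 2 of the 17 were higher (median 0.57), and with a pseudocount of 5 there were 7 (median 0.93). Of 6 mast cell and granulocyte genes 2 were higher, Tpsb2 (1.14) and Cma1 (1.05), and 0 lower (median 0.91, percentile 99.9), and the number higher was 4 with values as deposited or equal sums and 0 with a pseudocount of 5 or scaling to luminal genes. The members within 2-fold, named after their values had been seen, were the mast cell genes Mcpt4 (0.92) and Cpa3 (0.90) and the neutrophil genes S100a9 (0.40) and S100a8 (−0.27). The median thus mainly describes mast cell genes.

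Other cell types differed less or the other way. None of 14 endothelial genes differed by 2-fold after median-ratio scaling, and their median of 0.12 (percentile 85.7) was −0.45 with scaling to luminal genes. The endothelial members farthest from 0 were Vwf (8.38 against 2.98 RPKM, 0.90) and Cldn5 (26.4 against 10.7 RPKM, 0.84), and both passed 2-fold with values as deposited (1.24 and 1.23) and with equal sums (1.04 and 1.00). Of 19 lymphocyte and plasma cell genes 9 were lower and 1 higher (median −0.85, percentile 0), with 4 lower with values as deposited, 14 with scaling to luminal genes and 0 with a pseudocount of 5. The B cell gene Ms4a1 (0.236 against 2.49 RPKM, −1.68) and the T cell gene Cd8b1 (0.726 against 3.19 RPKM, −1.52) were lower. The higher member, named after its value had been seen, was Igj, the antibody J chain gene of plasma cells (1.15). Lymph nodes had been removed before extraction.

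Of 6 skeletal muscle genes Acta1 was higher (31.9 against 4.11 RPKM, 2.32) and Ckm (−1.77) and Tnni2 (−1.21) lower, with Tnni2 within 2-fold as deposited (−0.96). The median of −0.12 (percentile 19.3) depended on the settings, at 0.17 with values as deposited, 0.77 at a minimum mean of 5 RPKM and −0.84 without the filter. Of 3 skin keratinocyte genes Krt15 was lower (16.5 against 33.8 RPKM, −1.38, and −0.99 as deposited), with a list median of −0.41 (percentile 16.2) that was 0.02 without the filter on low values. Alas2, the only erythroid gene above the minimum, stood at 19.1 against 12.2 RPKM (0.22, percentile 68.6, −0.37 with scaling to luminal genes).

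Genes that mark the state of the tissue also differed. Of 29 proliferation genes 4 were lower and 0 higher (median −0.66, percentile 0), namely Mki67 (6.21 against 24.9 RPKM, −2.22), Rrm2 (−1.55), Ube2c (−1.09) and Ccna2 (−1.05), with 7 lower after quantile normalization, 21 with scaling to luminal genes and 2 with values as deposited, equal sums or a pseudocount of 5. Of 23 genes of involution, the regression of the gland after lactation, and of the acute phase, 13 were higher and 1 lower (median 1.19, percentile 100). Haptoglobin (Hp) stood at 235 against 29.9 RPKM (2.53), Igfbp5, a binding protein that restrains IGF1, at 996 against 130 RPKM (2.52) and Tgfb3 at 135 against 21.5 RPKM (2.19). The lower member, named after its value had been seen, was Clu (−1.22), within 2-fold with values as deposited (−0.80) and quantile normalization (−0.94). With scaling to luminal genes 6 of the 23 were higher (median 0.68), and with a pseudocount of 5 there were 8 (median 0.88). Of 25 immediate early and stress genes 14 were higher and 1 lower (median 1.17, percentile 100), with Fos at 63.6 against 7.45 RPKM (2.55), Junb at 44.0 against 5.60 (2.39), Cyr61 at 30.5 against 3.74 (2.37) and Fosb at 8.24 against 0.565 (2.30). The lower member, named after its value had been seen, was Gadd45g (−1.16), within 2-fold with values as deposited (−0.77) and with equal sums (−0.997). With scaling to luminal genes 10 of the 25 were higher (median 0.70), and with a pseudocount of 5 there were 9 (median 0.78). The heat shock genes of the list, named after their values had been seen, lay within 2-fold: Hspa1a (0.0), Hspa8 (−0.14), Hspa1b (−0.19) and Dnajb1 (−0.33). Genes of this list are known to respond within minutes to the handling of fresh tissue.

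Of 24 interferon-stimulated genes 3 were higher, Ifi27l2a (1.22), Oasl2 (1.13) and Gbp2 (1.07), and 0 lower. The median of 0.45 (percentile 99.9) was −0.05 with scaling to luminal genes, where 0 members were higher and 2 lower, and 6 were higher with values as deposited and 1 with a pseudocount of 5. Of 32 oxidative phosphorylation genes 3 were lower, Atp5g1 (−1.48), Cox5a (−1.22) and Atp5o (−1.02), of which only Atp5g1 was lower with values as deposited or quantile normalization, while 22 were lower with scaling to luminal genes (median −1.11). The median of −0.49 (percentile 1.53) lay inside the range of random lists. None of 35 cytosolic ribosome genes differed by 2-fold, and 2 were lower with scaling to luminal genes. Their median of −0.21 (percentile 53.4) was 0.19 with values as deposited and 0.03 with quantile normalization, and the members farthest from 0 were Rps25 (−0.43) and Rpl32 (−0.38, and 0.03 as deposited).

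Of the 27 lists, 18 had medians outside the central 99% of random lists, 9 below and 9 above. The same 18 lay outside with quantile normalization, while a scaling that shifts the genes nearly alike leaves this percentile almost unchanged by construction. With scaling to luminal genes the interferon list had a median of the opposite sign. Without the filter the brown adipocyte list lay inside the central 99% and the skeletal muscle list outside, and at a minimum mean of 5 RPKM the brown adipocyte, hormone-sensing luminal and lymphocyte lists lay inside. The spread between animals was not measured here, and a difference of any size in this section rests on 2 group means.

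**Figure D2:**
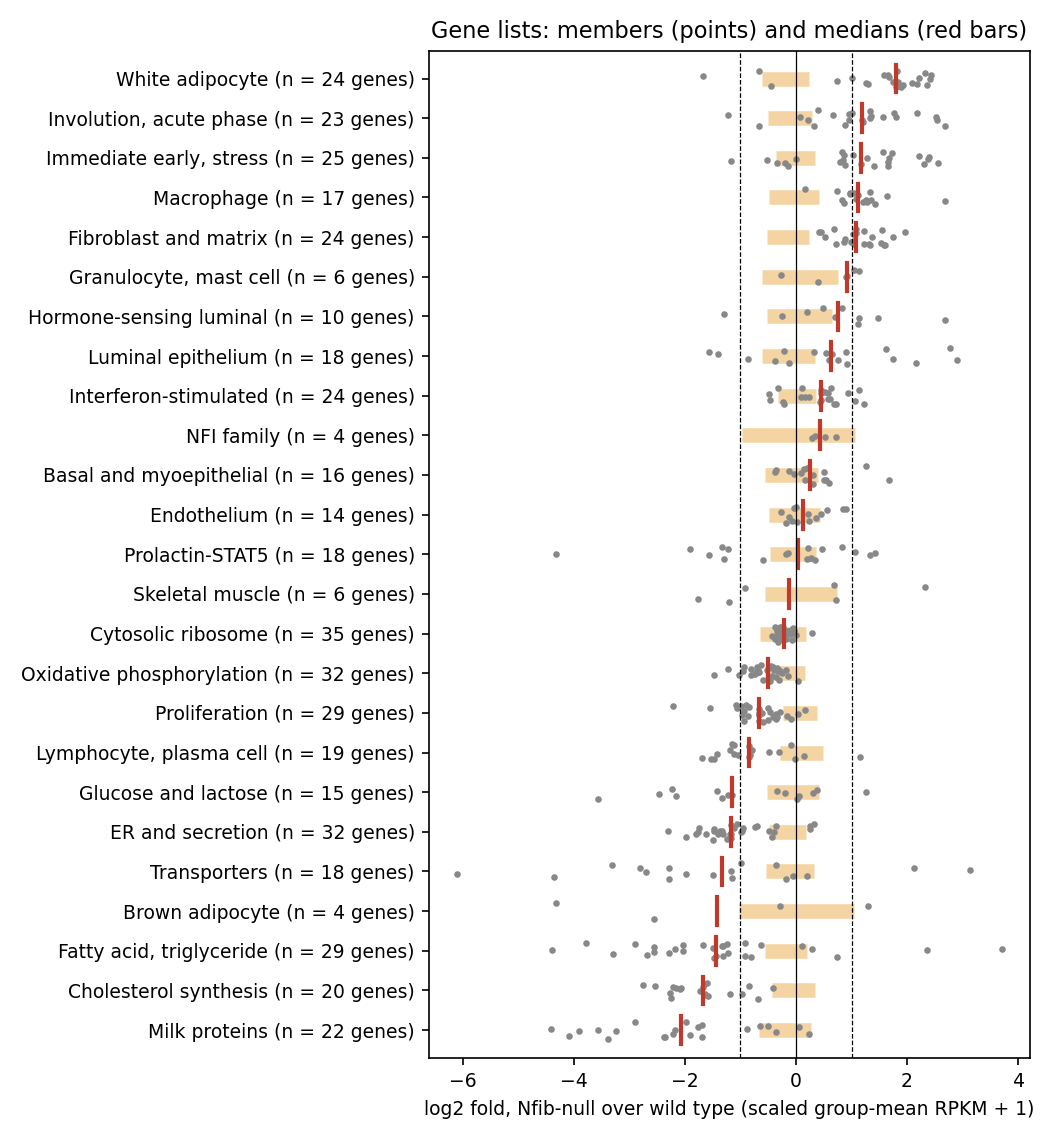
Points are the genes of each fixed list with at least 4 genes at a mean of 1 RPKM or more, placed by log2 fold (scaled group-mean RPKM + 1, Nfib-null over wild type), red bars are list medians, tan bars the central 99% of medians of 10000 random lists matched on expression, and dashed lines 2-fold. The milk protein median lies at −2.07 and the white adipocyte median at 1.81, both outside their tan bars.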

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

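No paired analysis was possible because the deposited columns give a single value per gene and group and carry no replicate number. For the same reason the planned limma alternatives, camera, fry, the permutation test and the omission of each library were not run. The fold limits of 1.5 and 4 and the scaling to luminal epithelial genes were chosen after seeing the data, as were the 2-fold limit and the random lists, while the other scalings, pseudocounts and filters were chosen before. The difference of Nfib lay between −0.32, with scaling to luminal genes, and the 0.70 of the values as deposited. With a pseudocount of 0.1 there were 1313 genes higher, and with 5 there were 790 beyond 2-fold, 346 higher and 444 lower, which the compression of low values by a larger pseudocount produces. Values as deposited gave 1800 higher and 369 lower. A limit of 1.5-fold gave 3978 (2145 higher, 1833 lower), and 4-fold gave 245 (91 and 154), by construction. Scaling to luminal genes gave 2855 (264 higher, 2591 lower), because it moves the median of all genes to −0.54. The milk protein share with the caseins, Wap and Lalba alone was 50.9% in the wild type and 24.8% in the Nfib-null column, by having fewer genes. The sign reversed for Csn1s1 with quantile normalization (0.77), which aligns the top ranks of both columns, and for the median of the brown adipocyte list without a filter (0.039), where genes with low values enter. Of 99 genes taken by the naming rule, Nfib apart, 81 kept their direction and side of 2-fold with scaling to luminal genes, 82 with a pseudocount of 5, 88 with values as deposited and 92 with quantile normalization. With 2 group means, what limits these results is the unmeasured spread between animals. Depth limits genes near 1 RPKM, with about 32.6 reads per kb in the wild type.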

Other observations

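All tests in this part were chosen after the results had been seen, and so were the lists on fatty acid oxidation and the circadian clock.

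In a list of fatty acid oxidation and genes regulated with it by PPAR receptors, written after Pdk4 and Angptl4 had been seen, 12 of the other 20 genes were at least 2-fold higher in the Nfib-null column, 8 lay within 2-fold and 0 were lower. The higher ones included the mitochondrial uncoupling protein Ucp3 (60.9 against 6.99 RPKM, 2.57), Cpt1a, which admits fatty acids to mitochondria (40.5 against 5.78 RPKM, 2.24), and the dehydrogenase Acadl (185 against 47.3 RPKM, 1.54). Adipose tissue also uses several of these genes, so the list is not separate from the adipocyte genes. Pthlh, the gene of the calcium-mobilising hormone that the lactating gland secretes, stood at 1.65 against 22.6 RPKM (−3.47), and Orai1, a calcium channel, at 26.7 against 88.0 RPKM (−2.09), beside the difference of the calcium pump gene Atp2b2. Atp2c1, another calcium pump gene, lay within 2-fold (54.0 against 46.1 RPKM, −0.18). Foxi1, a transcription factor of ion-transporting cells that drives proton pump genes in other tissues, stood at 38.4 against 6.14 RPKM (2.08), beside the proton pump gene Atp6v1b1. Pthlh, Orai1 and Foxi1 were picked after their values had been seen, with no list or count behind them.

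Single values stood out as well. The nuclear RNA Malat1 stood at 161 against 1051 RPKM (−3.11).

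Nfib was not lower in the Nfib-null column, with a log2 difference of 0.30 after scaling. The number of libraries behind each column argues against an exchange of the columns: 84.4% of the values with 10 decimals in the Nfib-null column, against 0% in the wild-type column, ended as a mean of 3 does, and the labels give 3 Nfib-null and 2 wild-type libraries. Reads from outside the deleted part, or from cells that keep the gene, could account for the 0.30. They cannot be told apart from an intact gene, since the whole-gene RPKM covers all of these and values per exon were not analysed here. A wrong label on a single library stays open, as group means cannot show it.

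Milk protein genes were lower and adipocyte genes higher in the Nfib-null column. A smaller share of epithelium, with its mix of cells and expression per cell unchanged, would lower luminal genes as much as milk genes. The lower quartile of the luminal list (−0.19), however, lay above the upper quartile of the milk protein list (−1.08). That list had 5 higher members, such as Kit (2.89), and 2 lower ones, such as Elf5 (−1.56). A changed mix of luminal cells therefore stays open, since the quartiles of the whole list do not address it. A larger share of every cell type outside the epithelium would raise endothelial genes with adipocyte genes, and the upper quartile of the endothelial list (0.44) lay below the lower quartile of the adipocyte list (1.28). A larger share of adipocytes stays open and cannot be told apart from higher expression per fat cell, since the count of 8 of the 10 most abundant adipocyte genes outside the lipid synthesis list at least 2-fold higher restates the pattern. Fibroblast (16 of 24), macrophage (11 of 17), involution (13 of 23) and immediate early genes (14 of 25) were higher beside them, with counts of 2, 2, 6 and 10 after scaling to luminal genes, so other cell types, the handling of tissue, dissection, litter and the genotype stay open as well.

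The circadian clock genes differed in opposite directions by arm. Dbp, a clock output gene, stood at 26.0 against 3.40 RPKM (2.26) and prompted the test. The other 11 genes driven by CLOCK and ARNTL had a median of 1.15, with 7 at least 2-fold higher and Hlf alone below 0 (−0.76), while the 5 genes of opposite phase, Arntl, Npas2, Clock, Cry1 and Nfil3, had a median of −1.20, with 4 at least 2-fold lower, or −0.88 and 1 with values as deposited. Tissue collected at different times of day or after different feeding could produce this. An effect of the genotype on the clock stays open as well, since the labels give no clock time.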
